A study of Mus musculus with 12 samples.

How the data were processed

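RNA-seq was made from 12 samples of mouse embryos at embryonic day 11.5, 3 pools of sorted cells in each of 4 populations: hematopoietic cluster cells (HC) and endothelial cells (EC) of the large arteries, each positive or negative for a Ly6a-GFP reporter. Per the labels' protocols, the embryos came from C57BL/6 x 129S1/SVImJ F1 females and Ly6a-GFP transgenic males, the arteries were dissociated with collagenase, cells were sorted into TRIzol-LS and pooled into independent biological samples, and libraries were made from poly(A)-selected RNA with an NEBNext Ultra kit. The labels do not say how many cells went into each pool. The sorted population and the replicate number of each library were taken from the sample titles.

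The authors deposited FPKM values (fragments per kilobase of transcript and per mapped fragments of the library) per gene symbol and library. Per the submitters' processing notes, Cufflinks, featureCounts, edgeR and DESeq were used and the genome build was mm9, with no roles or versions. The aligner, the annotation, the strand setting and any scaling between libraries are not given in the sources used here. The deposited FPKM values are estimates and not multiples of whole reads, so read numbers could not be recovered, the depth of each library is unknown, and no count test was run. An exact 0 may be a failed estimate, so such genes are described as listed at 0. FPKM sums differ between libraries, and the scalings named below test how far that matters. Values are relative within a library, so a change in a few abundant genes moves all others. Poly(A) selection leaves RNA without a tail to chance carry-over, so small nucleolar RNAs are measured less reliably, and genes with near-identical copies (globins, class I antigen genes, mitochondrial genes, pseudogenes) are uncertain because reads can be split between copies.

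Of 33531 genes, 11654 were at 0 in every library, and the 13278 with FPKM of 1 or more in at least 3 of the 12 libraries were tested. Values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3. One model with 4 group means and 8 residual degrees of freedom was fitted to all 12 libraries, with empirical Bayes moderation and an intensity trend of the prior variance. There were 5 comparisons: GFP+ against GFP− in HC and in EC, HC against EC among GFP+ and among GFP− cells, and the difference between the GFP effects of HC and EC. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all tested genes of a comparison, and the threshold was an adjusted p of 0.05. The pools were independent biological samples per the labels, so p-values measure the spread between pools of embryos.

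Before the data were examined, 28 gene lists with 540 distinct genes were fixed, for the sort markers, the gene under study and its ligand, hematopoietic stem cells, the endothelial-to-hematopoietic transition, blood lineages (lymphoid, granulocyte and monocyte, macrophage, erythroid, megakaryocyte and platelet, mast cell and basophil), pan-endothelial, arterial and venous identity, other cell types that the sorts could hold (smooth muscle and mesenchyme, epithelium and mesonephros, neural and neural crest, yolk sac endoderm and liver), cell cycle phases, interferon, NF-kB, TGF-beta and BMP, matrix, antigen presentation, glycolysis, dissociation stress, RNA quality and the Ly6 family near Ly6a. Older symbols were used where the values list a gene under one, such as Gpr56. Of the lists 27 had at least 5 tested members and were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over all 135 tests, and with an estimated correlation and with fry as alternatives. Counts of list members past the threshold are given over all tested genes and adjusted over the list alone. The list of the gene under study and its ligand had 1 tested member, Cd27, and was not tested as a list. A list score is the mean log2(FPKM + 1) of its tested members in a library.

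The genes named were chosen by a rule fixed beforehand. For each group comparison these were the sort markers with Cd27 and Cd70, the 6 genes with the largest rise and the 6 with the largest fall among those past the threshold, with no overlap between groups, a mean FPKM of 5 or more in the higher group and no clone or model name, and up to 4 members of a described list in the order of their p with the best member in the other direction. With 3 libraries against 3, chance alone separates the groups completely for 10% of genes, counted in both directions. For the difference of effects only the ranking by size was used. Genes named outside this rule are marked as chosen after their values were seen. Not every gene that the rule takes is described, pseudogenes among them, and the values of 1 gene are not reported here.

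Alternatives fixed beforehand were a pseudocount of 0.1, no filter (any gene above 0 in 1 library), a stricter filter (mean FPKM of 5 or more), scaling of libraries to an equal sum of FPKM, median-of-ratios scaling, quantile normalization, a fit of the groups compared alone, the replicate number as a block, a constant prior variance and leaving out each library in turn. A covariate of the macrophage or mesenchyme score, the same scores and the erythroid score centred within groups, and a correction for transcript length (a loess trend of span 0.3) were added after the data had been seen. Transcript lengths came from GENCODE vM21, which is built on another genome than mm9 and was used for lengths alone, and 99.4% of the tested genes had one. Families of TNF receptor and Hox genes were added later as lists for tests of hypotheses, with intervals from 10000 bootstrap draws over genes.

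The gene test was tested on simulated data with the real gene means and spreads. For GFP in HC, 31.3, 70.1 and 95.5% of the simulated changes of log2 0.5, 1 and 2 were recovered (67, 67 and 66 of 13278 genes) with 4.4% false calls. The shares were 29.9, 76.1 and 95.5% for GFP in EC (2.2% false), 32.8, 71.6 and 95.5% for HC against EC among GFP+ cells (6.3% false) and 31.3, 77.6 and 95.5% among GFP− cells (4.9% false). For the difference of effects they were 4.5, 53.7 and 86.4% (2% false), so most simulated differences of log2 0.5 were missed. In the list test, a simulated shift of 1 in the macrophage list was recovered and 0 of the other lists were called. The simulated genes varied independently of each other, so this does not tell how often correlated genes give false list calls. No library was left out of the main results, and no coordinates were used.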

Results

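Polyadenylated RNA was sequenced from 4 sorted cell populations of mouse embryos at embryonic day 11.5, a stage at which clusters of blood-forming cells sit on the endothelium of the large arteries. The dorsal aorta and the umbilical and vitelline arteries of 122 embryos were used, and the embryos carried a GFP reporter of Ly6a, which encodes the stem cell antigen Sca-1. Hematopoietic cluster cells (HC) were sorted as positive for CD31, VE-cadherin (CD144), ESAM and the receptor Kit, endothelial cells (EC) as positive for the same endothelial proteins but negative for Kit, and each type was split by GFP. The sorts gave 53000 GFP+ HC, 413000 GFP− HC, 377000 GFP+ EC and 791000 GFP− EC, which were pooled into 3 biological samples per population. Expression was given as FPKM, which keeps no read number, so the depth of the libraries is unknown. The FPKM of a library summed to between 555675 and 691948, and between 12147 and 12779 genes reached FPKM 1. Across genes, which are not independent replicates, the correlation of log2(FPKM + 1) was 0.956 to 0.979 in the 12 pairs of replicates and 0.899 to 0.968 in the 54 pairs from different populations. Levels below are mean FPKM ± SD with n = 3, and changes are log2 fold changes ± SE on the log2(FPKM + 1) scale, which understates the change of weakly expressed genes.

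The series is concerned with CD27, a receptor of the TNF receptor superfamily, as a marker of embryonic hematopoietic stem cells. Cd27 stood at 7.52 ± 3.26 FPKM in GFP+ HC, 0.771 ± 0.263 in GFP− HC, 1.02 ± 0.495 in GFP+ EC and 0.16 ± 0.14 in GFP− EC. It was 9.75-fold higher in GFP+ than in GFP− HC (log2 2.20 ± 0.28, adjusted p = 0.00117) and 7.41-fold higher in GFP+ HC than in GFP+ EC (log2 2.03 ± 0.28, adjusted p = 0.000883). The GFP+ and GFP− EC differed by 0.78 in Cd27 without passing the limma test (adjusted p = 0.0901). That value passed with a pseudocount of 0.1 (2.22) and with libraries scaled to an equal sum (1.12), and the effect of GFP on Cd27 was not shown to differ between HC and EC (difference 1.43, adjusted p = 0.151). Cd70, the ligand of CD27, was listed at 0 in all 12 libraries.

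The sort markers followed the gates in part. Ly6a was higher in the GFP+ cells of both types, at 5.83 ± 1.96 against 0.768 ± 0.709 FPKM in HC (log2 1.99 ± 0.37, adjusted p = 0.0109) and 8.76 ± 0.319 against 0.896 ± 0.728 in EC (log2 2.45 ± 0.37, adjusted p = 0.00152). With a pseudocount of 0.1 these changes were 3.25, no longer past the threshold, and 3.70. Kit stood at 35.5 ± 3.18 FPKM in GFP+ HC, 21.4 ± 3.84 in GFP− HC, 14 ± 0.62 in GFP+ EC and 16.3 ± 3.18 in GFP− EC. It was higher in HC than in EC among GFP+ cells (log2 1.28 ± 0.15, adjusted p = 0.000343), whereas among GFP− cells the difference of 0.38 did not pass (adjusted p = 0.193). The higher Kit in GFP+ than in GFP− HC (log2 0.72 ± 0.15, adjusted p = 0.0205) no longer passed without HC GFP+ replicate 1 (0.74) or 2 (0.65) without HC GFP− replicate 1 or 3 (0.65 each) and with the mesenchyme score as a covariate (0.60). Ptprc, which encodes the leukocyte antigen CD45, was at 10.3 ± 2.69 and 5.53 ± 2.55 FPKM in GFP+ and GFP− HC and at 0.474 ± 0.168 and 0.0922 ± 0.111 in the EC. Pecam1 and Cdh5, which encode CD31 and VE-cadherin, were lower in GFP+ HC than in GFP+ EC by log2 −0.65 (adjusted p = 0.00308) and −0.64 (adjusted p = 0.00776). Esam was at 175 ± 10.4 and 146 ± 36.1 FPKM in GFP+ and GFP− HC and at 262 ± 11.3 and 208 ± 21 in GFP+ and GFP− EC. Its difference between the GFP+ cells (log2 −0.58, adjusted p = 0.0186) no longer passed without HC GFP+ replicate 1 (−0.54) or 3 (−0.57) or EC GFP+ replicate 2 (−0.54). As a list, the 6 sort markers had a median of 0.50 between GFP+ and GFP− HC (2 higher and none lower, 3 and 0 adjusted over the list alone, adjusted p = 0.000795, and adjusted p = 0.156 with an estimated correlation), a call that ended with the mesenchyme score as a covariate (0.335).

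**Figure D1:**
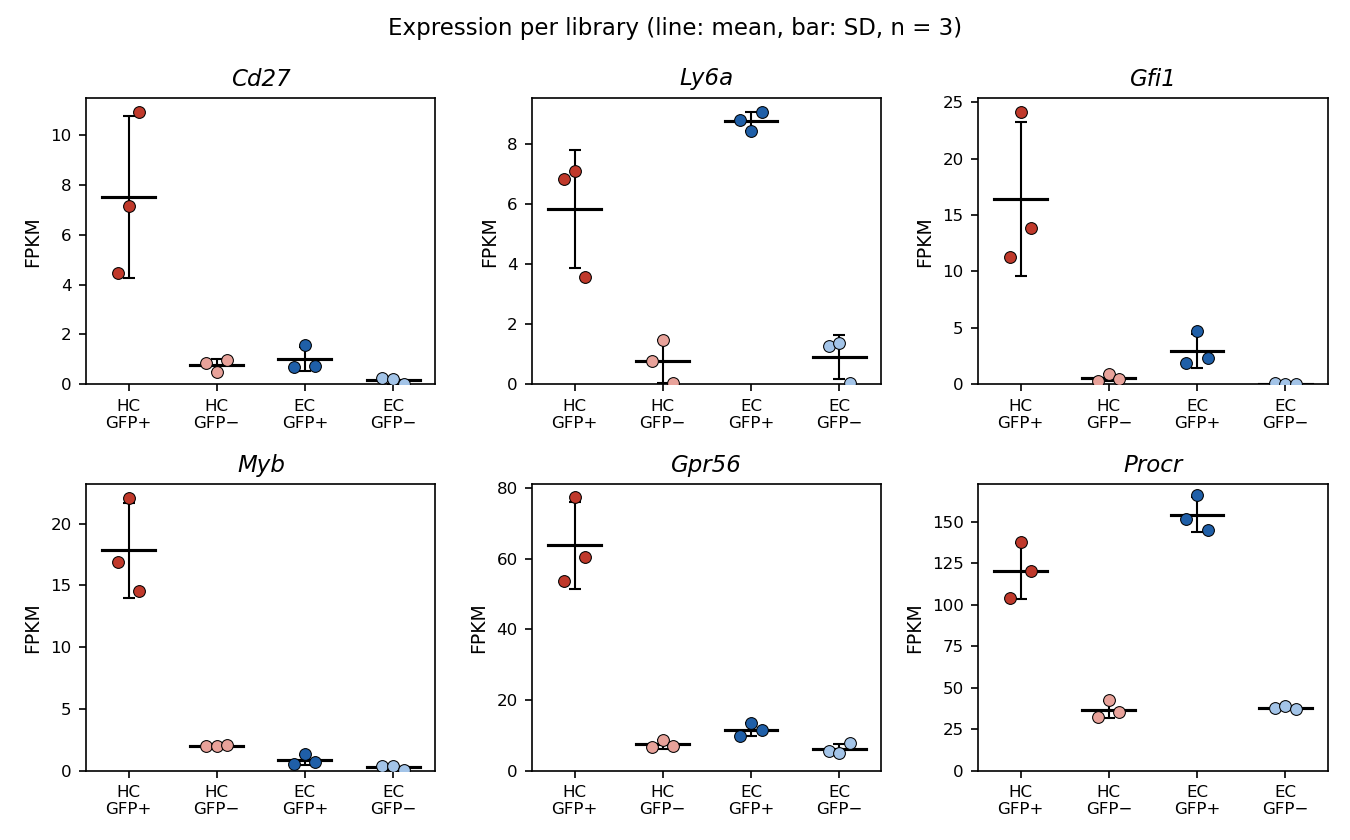
FPKM (vertical axes) of Cd27, Ly6a, Gfi1, Myb, Gpr56 and Procr in each library of hematopoietic cluster cells (HC) and endothelial cells (EC), GFP+ and GFP−, where points are libraries, lines are means and bars are SDs (n = 3). Cd27 lies at 4.46, 7.14 and 10.95 FPKM in the GFP+ HC libraries, and Procr is higher in the GFP+ cells of both types.

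GFP+ HC were compared with GFP− HC to ask what sets apart the cluster cells in which the Ly6a reporter is active. Regulators of blood stem and progenitor cells were higher in the GFP+ cells. Gfi1, a repressor that acts in the endothelial-to-hematopoietic transition, was at 16.4 ± 6.82 against 0.565 ± 0.302 FPKM (log2 3.42 ± 0.30, adjusted p = 9.77e-05), and Myb, a transcription factor of definitive blood progenitors, at 17.8 ± 3.86 against 2 ± 0.0448 (log2 2.63 ± 0.20, adjusted p = 4.31e-05). The adhesion receptor Gpr56 rose 8.62-fold (63.8 ± 12.3 against 7.4 ± 1.17 FPKM, adjusted p = 1.29e-05) and Spn, the sialophorin CD43 of the leukocyte surface, rose 14.7-fold (adjusted p = 6.04e-06). Procr, the protein C receptor found on stem cells, was at 121 ± 16.8 against 36.6 ± 5.18 FPKM (log2 1.69 ± 0.11, adjusted p = 1.89e-05). The other genes with the largest rises were Stmn2, which encodes a microtubule regulator (log2 2.45 ± 0.11), and the kinase gene Ptk2b (log2 2.40 ± 0.25).

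Of the 33 tested genes of the hematopoietic stem cell list, 11 rose in GFP+ HC, none fell and 22 did not pass, and adjusted over the list alone 16 rose and 1 fell. The list was called higher (median log2 0.43, camera adjusted p = 4.36e-08), also with an estimated correlation (adjusted p = 0.0252). Its members that rose included Mecom, a stem cell transcription factor (log2 0.92 ± 0.11). In the list of regulators of the endothelial-to-hematopoietic transition, which shares 5 genes with the stem cell list (Gata2, Gfi1, Itga2b, Myb and Runx1), 11 of 24 rose, none fell and 13 did not pass, and 15 rose adjusted over the list alone. This list was called higher too (median 0.57, adjusted p = 7.83e-15, and adjusted p = 0.018 with an estimated correlation). These were the only 2 of 17 list calls in this comparison that held with an estimated correlation.

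Some genes of the lineage lists were also higher in GFP+ HC. Of 15 granulocyte and monocyte genes 3 rose and none fell (4 and 0 adjusted over the list alone). The enzyme gene Mpo was at 20.1 ± 3.6 against 4.77 ± 1.78 FPKM (log2 1.90 ± 0.25, adjusted p = 0.00159). The list median was 0.66 (adjusted p = 0.000257, but adjusted p = 0.367 with an estimated correlation), and it was 1.07 without HC GFP+ replicate 2, 0.35 without HC GFP+ replicate 3, 0.37 without HC GFP− replicate 2 and 0.36 with no expression filter. Of 30 lymphoid genes 13 were tested, 2 rose and none fell (4 and 1 adjusted over the list alone). Flt3, a cytokine receptor of early progenitors, rose by log2 1.60 ± 0.16 (2.81 with a pseudocount of 0.1). Il2rg, the common cytokine receptor chain, rose by log2 1.02 ± 0.12. The lymphoid list median was 0.40 (adjusted p = 0.0424, and adjusted p = 0.192 with an estimated correlation). That call ended without HC GFP+ replicate 2 (0.55) or 3 (0.27), HC GFP− replicate 1 (0.50) or 3 (0.43), or EC GFP− replicate 2 or 3 (0.40 each). It ended too with a pseudocount of 0.1 (0.415), the stricter filter (0.322), libraries scaled to an equal sum (0.45), the HC libraries fitted alone (0.403) and the mesenchyme covariate (0.46), and with no filter the median was 0.076. Of 14 mast cell and basophil genes 5 were tested and 2 rose, the sort marker Kit and Srgn (serglycin, log2 1.77 ± 0.21). This list had a median of 0.80 (3 higher adjusted over the list alone, adjusted p = 0.000676, and adjusted p = 0.142 with an estimated correlation), which was 0.48 without HC GFP+ replicate 3 and 0.32 with no filter. Macrophage genes did not separate the HC by GFP: with limma 0 of 19 passed, 1 was higher at an unadjusted p under 0.05, and the list median was 0.37 (adjusted p = 0.217).

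Erythroid genes were lower in GFP+ HC. Of 25 tested genes 20 fell, 1 rose and 4 did not pass (21 and 1 adjusted over the list alone). The median was −1.75 (adjusted p = 1.21e-22, but adjusted p = 0.0874 with an estimated correlation), or −2.64 with the stricter filter. The embryonic globin Hbb-y was at 588 ± 81.8 against 4320 ± 1000 FPKM (log2 −2.86 ± 0.34, adjusted p = 0.000856), and Hbb-bh1, Hba-x, Hba-a1 and Hba-a2 fell by 2.90 to 3.06 on the log2 scale. Slc4a1, the anion exchanger of the red cell membrane, changed by −2.83 ± 0.32 and Alas2, the first enzyme of heme synthesis in red cells, by −2.38 ± 0.29. The member that rose was the transcription factor gene Nfe2 (log2 1.63 ± 0.32, adjusted p = 0.0144), which did not pass without HC GFP+ replicate 2 (1.51) or 3 (1.55) or without HC GFP− replicate 1 (1.59) or 3 (1.54). Globin genes share reads with near-identical copies, so the values of single globins are uncertain. Snora33, a small nucleolar RNA, was listed at 0 in all GFP+ HC and at 62.3, 21.17 and 43.31 FPKM in the GFP− HC, and its call ended without any 1 of the 6 HC libraries, with no filter and with the mesenchyme covariate. No fold is given for it.

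Endothelial and arterial genes differed member by member between GFP+ and GFP− HC. Vwf, the von Willebrand factor of endothelium and platelets, was at 174 ± 19.5 against 33.6 ± 6.19 FPKM (log2 2.35 ± 0.14, adjusted p = 6.59e-06). The arterial gap junction gene Gja5 (log2 2.32 ± 0.17) and the Notch ligand gene Jag1 (log2 1.08 ± 0.12) rose, whereas Unc5b, a netrin receptor of arterial endothelium, fell (log2 −1.57 ± 0.11, adjusted p = 1.89e-05). In the arterial and Notch list 7 of 26 rose and 2 fell (11 and 4 adjusted over the list alone), and its median of 0.05 was called at adjusted p = 0.0407 (adjusted p = 0.595 with an estimated correlation), a call that ended without HC GFP+ replicate 2 (0.11), HC GFP− replicate 1 (−0.01) or 3 (0.08), or EC GFP− replicate 3 (0.05). It ended too with the stricter filter (0.051), libraries scaled to an equal sum (0.097), the HC libraries fitted alone (0.052) and the mesenchyme covariate (0.067), and the median was 0.127 without HC GFP− replicate 2. Prox1, the regulator of lymphatic identity, fell (log2 −1.90 ± 0.15, adjusted p = 6.23e-05), as did Flt4, the VEGF-C receptor (log2 −0.91 ± 0.15). The venous and lymphatic list, with 1 of 14 higher and 3 lower (1 and 4 adjusted over the list alone), was not called (median −0.06, adjusted p = 0.254). Of 26 pan-endothelial genes 2 rose and none fell, also adjusted over the list alone. The median was 0.15 (adjusted p = 0.00506, but adjusted p = 0.678 with an estimated correlation). That call ended without HC GFP+ replicate 2 (0.098) or HC GFP− replicate 1 (0.081) or 3 (0.095), and the median was 0.30 without HC GFP− replicate 2. With the mesenchyme score as a covariate it was 0.008 and the direction of the test reversed. In the list of smooth muscle and mesenchyme, 0 of 23 passed with limma while 8 were lower at an unadjusted p under 0.05 (0 adjusted over the list alone). The median was −0.80 (adjusted p = 3.39e-06, but adjusted p = 0.492 with an estimated correlation).

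Some immune response genes were higher in GFP+ HC. Of 26 interferon response genes 4 rose and none fell (11 and 0 adjusted over the list alone), and 18 were higher at an unadjusted p under 0.05. The list median was 0.80 (adjusted p = 9.01e-11, but adjusted p = 0.273 with an estimated correlation), and 0.42 without HC GFP+ replicate 3. That library had a mean interferon list score of 4.15, against 3.23 and 2.97 in the other GFP+ HC and 2.63, 2.27 and 2.86 in the GFP− HC, and the highest macrophage score of the 12 libraries, 6.23. Irf9, a subunit of the interferon-activated factor, rose (log2 0.76 ± 0.14, adjusted p = 0.0117) but did not pass without HC GFP+ replicate 3 (0.67). The calls of Xaf1 (log2 1.45), Ifitm1 (log2 1.99) and Oasl2 (log2 1.69) ended too without single libraries: Xaf1 without HC GFP− replicate 1 (1.38) or 2 (1.28), Ifitm1 without any 1 of the 6 HC libraries (1.73 to 2.18) and Oasl2 without any library except HC GFP+ replicate 2 (1.13 to 1.90). Ifitm1 also lost its call with a pseudocount of 0.1 (2.05) and Oasl2 with the mesenchyme covariate (1.85). Of 11 antigen presentation genes, 3 of which are in the interferon list, 1 rose and none fell (8 and 0 adjusted over the list alone). The median was 0.85 (adjusted p = 3.47e-06, and adjusted p = 0.266 with an estimated correlation). The one that rose was H2-D1, a class I gene that shares reads with its paralogs (log2 1.29 ± 0.18). Of 26 NF-kB and inflammatory genes 1 rose, Selp, which encodes P-selectin (log2 1.66 ± 0.19, and 3.63 with a pseudocount of 0.1), and none fell (3 and 0 adjusted over the list alone). The median of 0.41 (adjusted p = 0.000136, and adjusted p = 0.333 with an estimated correlation) was 0.15 without HC GFP+ replicate 3.

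Few genes of proliferation, stress and RNA quality passed in HC. With limma 0 of 20 genes of G2 and M phase passed, 5 were lower at an unadjusted p under 0.05 and 2 were lower adjusted over the list alone. The median was −0.11 (adjusted p = 0.000254, and adjusted p = 0.142 with an estimated correlation), or −0.07 with libraries scaled to an equal sum. The 22 S phase genes were not called (0 past the threshold with limma, 2 lower at an unadjusted p under 0.05, median −0.08, adjusted p = 0.0536). Of 18 glycolysis genes 1 fell and none rose, also adjusted over the list alone, namely the phosphofructokinase gene Pfkp (log2 −0.54 ± 0.09). The median of −0.11 (adjusted p = 0.00777, but adjusted p = 0.492 with an estimated correlation) was not called without HC GFP+ replicate 1 (−0.103) or HC GFP− replicate 2 (−0.105) or after quantile normalization (−0.107), and was −0.071 with libraries scaled to an equal sum. Of 20 dissociation stress and immediate early genes 3 rose, the transcription factor genes Klf2 (log2 0.81 ± 0.14), Klf4 (log2 0.97) and Nr4a1 (log2 0.84), and none fell (5 and 0 adjusted over the list alone). The median was 0.39 (adjusted p = 1.01e-05, and adjusted p = 0.217 with an estimated correlation), or 0.25 without HC GFP+ replicate 3. Mitochondrially encoded genes took 4.96, 4.34 and 3.8% of the summed FPKM in the GFP+ HC libraries and 5.11, 5.34 and 5.73% in the GFP− HC libraries. In the RNA quality list 2 of 14 fell and none rose (5 and 0 adjusted over the list alone). The median was −0.42 (adjusted p = 0.00164, but adjusted p = 0.4 with an estimated correlation), or −0.28 without HC GFP+ replicate 3, and it was −0.221 and not called after quantile normalization. Matrix genes went both ways (3 of 24 higher and 3 lower, 4 and 4 adjusted over the list alone, median −0.065, adjusted p = 0.612). Elastin (Eln, log2 1.83 ± 0.32) and biglycan (Bgn, log2 0.58 ± 0.09) were among those that rose, and the collagen gene Col15a1 (log2 −0.95 ± 0.17) among those that fell. The TGF-beta and BMP list was not called (0 of 21 past the threshold with limma, 2 higher and 2 lower at an unadjusted p under 0.05, median −0.04, adjusted p = 0.773).

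In the limma test of all 13278 genes, 566 differed between GFP+ and GFP− HC at an adjusted p of 0.05, 396 higher and 170 lower, and 211 of them changed at least 2-fold. The count was 363 with the stricter expression filter and 928 with a mesenchyme score centred within groups as a covariate. It was 337 without HC GFP+ replicate 3 and 349, 361 and 321 without HC GFP− replicates 1, 2 and 3.

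**Figure D2:**
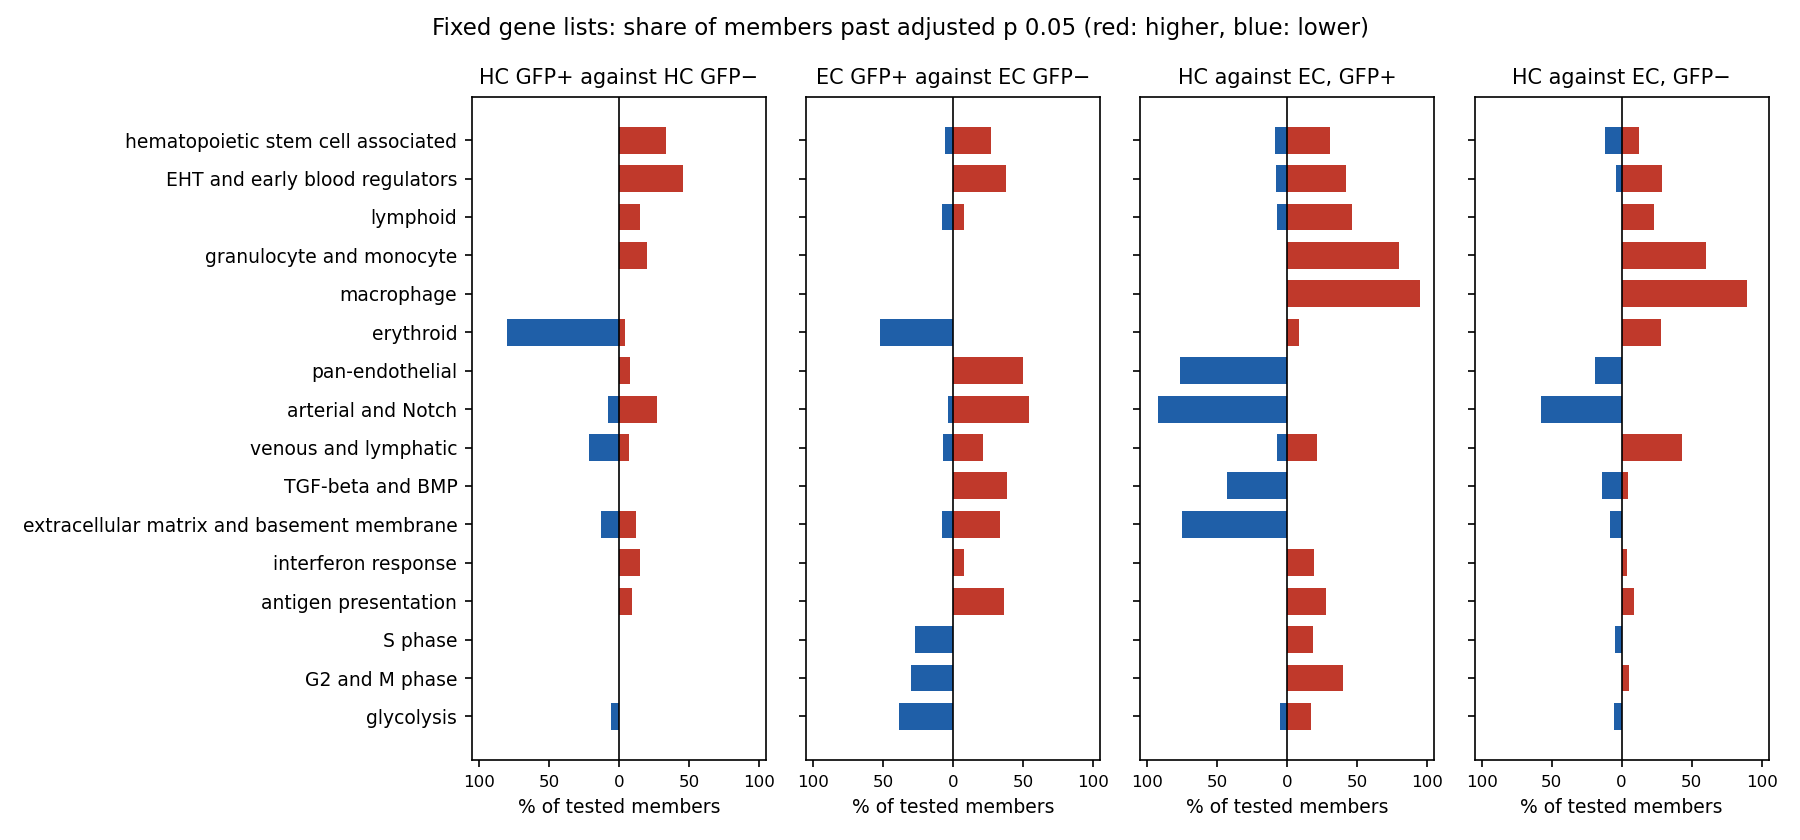
Percent of the tested genes of 16 lists (horizontal axes) past an adjusted p of 0.05 in each of the 4 group comparisons of hematopoietic cluster cells (HC) and endothelial cells (EC), where bars to the right in red are genes higher in the group named first and bars to the left in blue are genes lower in it. Of 25 erythroid genes 20 are lower in GFP+ than in GFP− HC, and of 26 arterial and Notch genes 24 are lower in GFP+ HC than in GFP+ EC.

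GFP+ EC were compared with GFP− EC to ask the same of endothelium. Arterial genes and single genes of secreted and matrix proteins were higher in the GFP+ cells. Eln, the elastin gene, was at 281 ± 74.6 against 14.7 ± 3.06 FPKM (19.2-fold, log2 4.16 ± 0.32, adjusted p = 1.51e-05), and Fbln5, a fibulin that assembles elastic fibres, changed by 3.4 ± 0.25 (adjusted p = 1e-05). The secreted protease gene Htra1 was at 96.8 ± 8.87 against 5.6 ± 1.64 FPKM (17.3-fold, adjusted p = 8.11e-07), and the genes of the secreted proteins Cytl1 and Pi16 (3.55 each on the log2 scale) and of the calcium-binding protein S100a4 (3.25) also rose. The gap junction gene Gja5 (log2 2.71 ± 0.17), the Notch ligand gene Jag1 (log2 2.27 ± 0.12), the Notch target gene Hey2 (log2 2.59 ± 0.20) and Ltbp4, a latent TGF-beta binding protein (log2 2.82 ± 0.16), were the 4 arterial genes with the smallest p, and Igfbp3, an insulin-like growth factor binding protein, went the other way (log2 −1.08 ± 0.18). In that list 14 of 26 rose and 1 fell (17 and 2 adjusted over the list alone). The median was 0.70 (adjusted p = 5.05e-11, and adjusted p = 0.142 with an estimated correlation).

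Other endothelial, signalling and matrix genes were higher in GFP+ EC as well. Of 26 pan-endothelial genes 13 rose and none fell (15 and 0 adjusted over the list alone). The median was 0.36 (adjusted p = 2.63e-10, but adjusted p = 0.333 with an estimated correlation), while the mesenchyme list was lower in the same cells (median −0.65). It was 0.209 with the mesenchyme score as a covariate and 0.534 after quantile normalization. The angiopoietin receptor gene Tek rose (log2 1.19 ± 0.15). Of 21 TGF-beta and BMP genes 8 rose and none fell (10 and 0 adjusted over the list alone), among them Bmp6 (log2 2.19 ± 0.17) and the inhibitory Smad genes Smad6 (log2 1.46 ± 0.11) and Smad7 (log2 0.95). This list (median 0.205, adjusted p = 1.87e-05) was the only 1 of 16 called in this comparison that held with an estimated correlation (adjusted p = 0.0201), and its median was 0.32 without EC GFP+ replicate 2 and 0.33 without EC GFP− replicate 3. Of 24 matrix genes 8 rose and 2 fell (12 and 4 adjusted over the list alone). The median was 0.41 (adjusted p = 8.12e-06, and adjusted p = 0.098 with an estimated correlation). The fibrillin gene Fbn1 rose (log2 1.93 ± 0.14) and Col15a1 fell (log2 −0.94). With libraries scaled to an equal sum, which moved the median of all genes from −0.03 to 0.15, the pan-endothelial, TGF-beta and matrix medians were 0.56, 0.406 and 0.61. Prox1 fell (log2 −0.83) while the venous receptor gene Ephb4 rose (log2 0.57) in the venous and lymphatic list, which was not called (3 of 14 higher and 1 lower, 5 and 2 adjusted over the list alone, median 0.25, adjusted p = 0.102).

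Blood stem cell genes also differed between the EC. Procr was at 154 ± 10.6 against 37.8 ± 0.843 FPKM (log2 2 ± 0.11, adjusted p = 1.87e-06). Of 33 stem cell genes 9 rose and 2 fell (10 and 3 adjusted over the list alone). The median was 0.235 (adjusted p = 0.00353, and adjusted p = 0.157 with an estimated correlation), or 0.16 without EC GFP− replicate 2 and 0.44 with libraries scaled to an equal sum. Gata2, a regulator of hemogenic endothelium, rose (log2 0.94 ± 0.12) and the cell cycle inhibitor gene Cdkn1c fell (log2 −0.49 ± 0.08, and −0.29 under that scaling). Of 24 regulators of the endothelial-to-hematopoietic transition 9 rose and none fell (13 and 0 adjusted over the list alone), including Smad6, the transcription factor gene Lyl1 (log2 0.93) and Bmp4 (log2 0.69). This list shares 3 genes (Bmp4, Smad6 and Smad7) with the TGF-beta and BMP list. The median was 0.45 (adjusted p = 1.97e-07, and adjusted p = 0.0612 with an estimated correlation), or 0.675 with libraries scaled to an equal sum. With limma 0 of 15 granulocyte and monocyte genes passed (2 higher and 1 lower at an unadjusted p under 0.05, median 0.13, adjusted p = 0.491) and 0 of 19 macrophage genes (0 at an unadjusted p under 0.05). The macrophage median of −0.02 differed in sign from the mean of 0.05 and the direction of the test (adjusted p = 0.701). In the lymphoid list 1 of 13 rose, Il2rg (log2 1.22 ± 0.12), and 1 fell (median 0.07, adjusted p = 0.536).

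Some erythroid, cell cycle, glycolytic and mitochondrial genes were lower in GFP+ EC. Of 25 erythroid genes 13 fell and none rose (17 and 0 adjusted over the list alone). The median was −0.93 (adjusted p = 1.06e-07, but adjusted p = 0.273 with an estimated correlation), and Hbb-y changed by −1.80 ± 0.34 (adjusted p = 0.00597). That median was −1.44 with a pseudocount of 0.1 and −1.48 with the stricter filter. Of 22 S phase and 20 G2 and M phase genes 6 each fell and none rose (6 and 9 adjusted over the lists alone), and the cyclin gene Ccne2 fell by 0.90 on the log2 scale. The medians of −0.18 each (adjusted p = 0.000304 and 0.000343, but adjusted p = 0.217 and 0.144 with an estimated correlation) became 0.014 and 0.015 with libraries scaled to an equal sum, and neither was then called. Of 18 glycolysis genes 7 fell and none rose (8 and 0 adjusted over the list alone), and Gapdh fell by 0.88 on the log2 scale. The median was −0.35 (adjusted p = 0.000238, and adjusted p = 0.333 with an estimated correlation), or −0.15 with libraries scaled to an equal sum and −0.168 after quantile normalization. Mitochondrially encoded genes took 5.93, 6.47 and 4.66% of the summed FPKM in the GFP+ EC libraries and 8.53, 8.74 and 8.76% in the GFP− EC libraries, and mt-Nd6, a subunit of respiratory complex I, was at 115 ± 35.3 against 495 ± 85.6 FPKM. In the RNA quality list 6 of 14 fell and none rose (8 and 0 adjusted over the list alone). The median was −0.66 (adjusted p = 0.000289, and adjusted p = 0.333 with an estimated correlation), or −0.39 after a length correction, and it was −0.27 and no longer called after quantile normalization. Of 23 mesenchyme genes 1 fell (0 adjusted over the list alone, 9 lower at an unadjusted p under 0.05). The median was −0.65 (adjusted p = 0.00164, but adjusted p = 0.666 with an estimated correlation). That median was −0.445 and not called without EC GFP− replicate 3, −1.14 without EC GFP− replicate 2, −0.989 with a pseudocount of 0.1 and −1.128 with the stricter filter.

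Besides mt-Nd6 and Hbb-y, the 6 largest falls in GFP+ EC were those of Fgf12 (log2 −2.25, adjusted p = 0.0271), the globin gene Hbb-bh1 (−1.92, adjusted p = 0.0151), the ion transport regulator gene Fxyd1 (−1.89, adjusted p = 0.0498) and Lum, which encodes the matrix proteoglycan lumican (−1.89, adjusted p = 0.047). The call of Hbb-bh1 ended without EC GFP+ replicate 1 (−1.57) or 3 (−1.78) or EC GFP− replicate 3 (−1.53), and that of Fgf12 without any 1 EC library except GFP− replicate 2 (−2.39 to −1.58). The call of Fxyd1 ended without any library except HC GFP− replicate 2 or EC GFP− replicate 2 (−2.10 to −1.23), and that of Lum without any library except these and HC GFP+ replicate 1 (−2.15 to −1.48). All 4 calls ended with only the EC libraries fitted, and those of Fgf12, Fxyd1 and Lum with no filter. With the mesenchyme covariate Fgf12 (−1.90) and Fxyd1 (−1.03) did not pass, and with a pseudocount of 0.1 they were at −4.19 and −3.62. A constant prior variance and a length correction ended the calls of Fxyd1 (−1.89 and −1.62) and Lum (−1.89 and −1.83), median-of-ratios scaling that of Fxyd1 (−1.88), and equal-sum scaling and quantile normalization that of Lum (−1.71 and −1.81).

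Some stress and immune genes were higher in GFP+ EC. Of 20 stress and immediate early genes 5 rose and none fell, also adjusted over the list alone, with Klf2 (log2 1.24), Klf4 (log2 1.23), Btg2 and Dusp1 (0.73 each) as examples and a median of 0.41 (adjusted p = 7.93e-05, and adjusted p = 0.258 with an estimated correlation). Of 11 antigen presentation genes 4 rose and none fell, also adjusted over the list alone, including H2-D1 (log2 1.19). The median was 0.69 (adjusted p = 0.000686, and adjusted p = 0.418 with an estimated correlation), or 0.29 with no filter and 1.194 with the stricter filter. Of 26 interferon response genes 2 rose and none fell, also adjusted over the list alone. The median was 0.385 (adjusted p = 0.000367, but adjusted p = 0.559 with an estimated correlation), or 0.633 with a pseudocount of 0.1 and 0.591 with libraries scaled to an equal sum. The NF-kB list was not called (3 of 26 higher, also adjusted over the list alone, median 0.10, adjusted p = 0.112).

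In the limma test, 1789 genes differed between GFP+ and GFP− EC, 924 higher and 865 lower, and 350 changed at least 2-fold. The split was 1934 higher and 288 lower with libraries scaled to an equal sum, 1044 and 603 with median-of-ratios scaling and 1035 and 595 after a length correction, so the balance of directions depends on the scaling. The count was 939 when only the EC libraries were fitted, and 1097, 1004 and 1146 without EC GFP+ replicate 1, EC GFP+ replicate 3 and EC GFP− replicate 3.

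The effects of GFP in HC and EC, which rest on separate libraries, overlapped. Of the genes past the threshold, 246 were higher in the GFP+ cells of both types where independent lists would share 27.6, and 94 were lower in both where independent lists would share 11.1, while 0 went in opposite directions. Vwf, Gja5, Procr, Stmn2 and Eln rose in both, and Hbb-y and Prox1 fell in both. Gfi1, named here for EC after its values were seen, rose by 1.88 in EC.

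**Figure D3:**
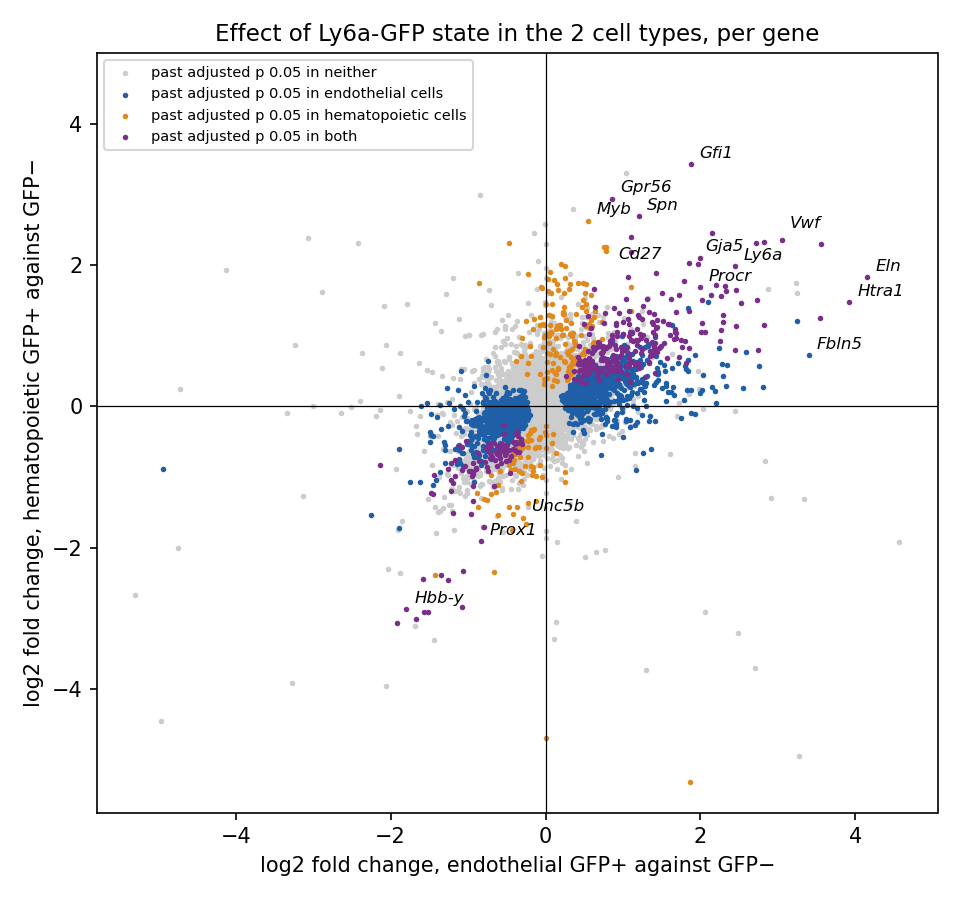
Log2 fold change of each tested gene between GFP+ and GFP− endothelial cells (EC, horizontal axis) and between GFP+ and GFP− hematopoietic cluster cells (HC, vertical axis), with each point a gene coloured by the comparison in which it passed an adjusted p of 0.05. Of the genes past the threshold in both, 246 lie at upper right and 94 at lower left, and Gfi1 has the values 1.88 and 3.42.

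Among GFP+ cells, HC were compared with EC to ask what distinguishes cluster cells from the endothelium with the same reporter state. Macrophage genes led the genes higher in HC. The complement genes C1qb (206 ± 168 against 4.63 ± 4.02 FPKM, log2 5.09 ± 0.72, adjusted p = 0.00107), C1qc (log2 5.08) and C1qa (log2 4.63) were at the top with the adaptor gene Tyrobp (log2 4.85), the chemokine gene Ccl3 (log2 4.66) and Csf1r, the macrophage growth factor receptor (log2 4.54). Of 19 macrophage genes 18 rose and none fell, also adjusted over the list alone. The median was 3.81 (adjusted p = 2.38e-15, but adjusted p = 0.217 with an estimated correlation). The macrophage list score was 5.26, 3.94 and 6.23 in the GFP+ HC libraries and 1.39, 1.12 and 2.06 in the GFP+ EC libraries. Of 15 granulocyte and monocyte genes 12 rose and none fell, also adjusted over the list alone. The median was 2.29 (adjusted p = 3.09e-10, and adjusted p = 0.156 with an estimated correlation), or 1.31 with no filter. Spi1, which encodes the myeloid transcription factor PU.1, rose by 4.29 ± 0.37 and Mpo by 3.41 ± 0.25.

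Several blood progenitor and immune genes were also higher in GFP+ HC. No macrophage covariate was fitted for HC against EC, so a macrophage source was not tested. Myb rose 20.8-fold (log2 3.35 ± 0.20, adjusted p = 6.29e-06). Runx1 was at 13.9 ± 1.92 against 1.02 ± 0.169 FPKM (log2 2.88 ± 0.27), and Gfi1 (log2 2.14) and Ikzf1 (log2 3.30) also rose. Of 24 regulators of the endothelial-to-hematopoietic transition 10 rose and 2 fell (12 and 3 adjusted over the list alone). The median was 0.24 (adjusted p = 0.00164, and adjusted p = 0.201 with an estimated correlation). The stem cell list was not called (10 of 33 higher and 3 lower, 13 and 8 adjusted over the list alone, median 0.04, adjusted p = 0.413), and Cd34 was its lower member with the smallest p (log2 −0.92). Of 13 lymphoid genes 6 rose and 1 fell (7 and 1 adjusted over the list alone, median 0.63, adjusted p = 0.00192, and adjusted p = 0.0799 with an estimated correlation), a median that was 0.38 without EC GFP+ replicate 2, 0.137 with no filter, and 0.165 and not called with the stricter filter. Notch1 fell (log2 −0.86). Of 26 NF-kB and inflammatory genes 12 rose and 1 fell, also adjusted over the list alone, with the cytokine gene Tnf at log2 3.07 and Ccl2 at 3.14 (median 0.65, adjusted p = 0.00184, and adjusted p = 0.427 with an estimated correlation), and of 26 interferon genes 5 rose and none fell (10 and 0 adjusted over the list alone, median 0.63, adjusted p = 5.81e-05, and adjusted p = 0.492 with an estimated correlation). The interferon median was 0.33 without HC GFP+ replicate 3. Of 20 genes of G2 and M phase 8 rose and none fell (11 and 0 adjusted over the list alone, median 0.235, adjusted p = 0.000291, and adjusted p = 0.142 with an estimated correlation), and of 22 S phase genes 4 rose and none fell (5 and 0 adjusted over the list alone, median 0.17, adjusted p = 0.00739, and adjusted p = 0.339 with an estimated correlation). The S phase median was 0.104 after a length correction.

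Arterial, endothelial and matrix genes were lower in GFP+ HC than in GFP+ EC. The gap junction genes Gja5 (33.8 against 269 FPKM, log2 −2.99 ± 0.17, adjusted p = 5.52e-06) and Gja4 (23.1 against 186 FPKM, log2 −2.97 ± 0.14), with Htra1, Fbln5, Eln and Gkn3, an arterial gastrokine (log2 −2.76 ± 0.29, and −4.78 with a pseudocount of 0.1), fell by 2.76 to 3.06 on the log2 scale. Of 26 arterial and Notch genes 24 fell and none rose (25 and 0 adjusted over the list alone). The median was −1.40 (adjusted p = 2.52e-31, and adjusted p = 0.0201 with an estimated correlation). Of 26 pan-endothelial genes 20 fell and none rose (22 and 0 adjusted over the list alone). The median was −0.62 (adjusted p = 8.84e-17, but adjusted p = 0.217 with an estimated correlation), and the endothelial nitric oxide synthase gene Nos3 fell by 1.03 on the log2 scale. Of 24 matrix genes 18 fell and none rose, also adjusted over the list alone (median −0.73, adjusted p = 2.38e-15, and adjusted p = 0.018 with an estimated correlation), and the fibronectin gene Fn1 fell by 1.34. Of 21 TGF-beta and BMP genes 9 fell and none rose (12 and 0 adjusted over the list alone, median −0.56, adjusted p = 2.94e-09, and adjusted p = 0.00933 with an estimated correlation), with the BMP target gene Id1 at log2 −1.10 ± 0.10. That median was −0.331 with the stricter filter. The arterial, matrix and TGF-beta calls were the 3 of 14 that held with an estimated correlation. The erythroid list was not called (2 of 25 higher and none lower, also adjusted over the list alone, adjusted p = 0.951), and its median of −0.12 differed in sign from its mean of 0.09 and the test.

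In the limma test, 1898 genes differed between HC and EC among GFP+ cells, 1090 higher in HC and 808 lower, and 609 changed at least 2-fold. The split was 859 higher and 971 lower with median-of-ratios scaling, 950 and 1069 after quantile normalization and 929 and 1067 after a length correction. Without EC GFP+ replicate 1 the count was 1261.

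Among GFP− cells, the same comparison of HC with EC again had macrophage genes at the top, beside Snora33, which was listed at 0 in the GFP− EC and lost its call with no filter and without HC GFP− replicate 1 or 3 or any 1 of the GFP− EC libraries. C1qb was at 141 ± 72 against 3.14 ± 1.51 FPKM (log2 5 ± 0.72, adjusted p = 0.00599), and Tyrobp (log2 5.08), C1qa (log2 4.95), Csf1r (log2 4.65) and C1qc (log2 4.64) followed. Of 19 macrophage genes 17 rose and none fell (18 and 0 adjusted over the list alone). The median was 3.65 (adjusted p = 3.82e-21, but adjusted p = 0.156 with an estimated correlation). The list score was 5.37, 3.87 and 5.15 in the GFP− HC and 1.35, 1.48 and 1.60 in the GFP− EC. Of 15 granulocyte and monocyte genes 9 rose and none fell (11 and 0 adjusted over the list alone, median 1.43, adjusted p = 4.08e-10, and adjusted p = 0.156 with an estimated correlation), and Spi1 rose by 3.67 ± 0.37. The granulocyte and monocyte median was 0.508 with no filter and 2.258 with a pseudocount of 0.1. The arterial genes Gja5 (5.88 against 40.4 FPKM, log2 −2.60 ± 0.17, adjusted p = 3.68e-05), Gja4 (log2 −2.33 ± 0.14), Cxcr4, the chemokine receptor (log2 −1.96 ± 0.19), and Hey1, a Notch target (log2 −1.55 ± 0.14), were lower in GFP− HC, as was the semaphorin gene Sema7a (log2 −1.73 ± 0.14).

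Of 26 arterial and Notch genes 15 fell in GFP− HC and none rose (19 and 0 adjusted over the list alone, median −0.68, adjusted p = 1.72e-21, and adjusted p = 0.0441 with an estimated correlation). Venous and lymphatic genes went the other way: 6 of 14 rose and none fell (8 and 0 adjusted over the list alone, median 0.63, adjusted p = 6.57e-07, and adjusted p = 0.0481 with an estimated correlation), with Prox1 at log2 1.36 ± 0.15, the hyaluronan receptor gene Lyve1 at 2.23 ± 0.28 and the neuropilin gene Nrp2 at 0.69. The list shares 2 genes, Maf and Mrc1, with the macrophage list, and Lyve1 is known from both lymphatic endothelium and macrophages. Of 13 lymphoid genes 3 rose and none fell (4 and 0 adjusted over the list alone, median 0.39, adjusted p = 0.000279, and adjusted p = 0.0441 with an estimated correlation). That median was 0.07 with no filter, 0.215 after quantile normalization and 0.589 with equal-sum scaling. A macrophage source was not tested. Of 18 calls only the arterial, venous and lymphoid held with an estimated correlation. Of 25 erythroid genes 7 rose and none fell (14 and 0 adjusted over the list alone, median 0.71, adjusted p = 5.45e-10, and adjusted p = 0.217 with an estimated correlation), including Kel, a red cell surface antigen (log2 2.02 ± 0.31). Of 24 regulators of the endothelial-to-hematopoietic transition 7 rose and 1 fell (7 and 3 adjusted over the list alone, median 0.17, adjusted p = 0.00213, and adjusted p = 0.215 with an estimated correlation), with Myb at log2 1.27 ± 0.20 and Ikzf1 at 2.05 ± 0.19, or 2.74 and 3.20 with a pseudocount of 0.1. The median of this list was 0.05 without HC GFP− replicate 2, 0.27 without HC GFP− replicate 3 and 0.305 with libraries scaled to an equal sum. The stem cell list was not called (4 of 33 higher and 4 lower, also adjusted over the list alone, median 0.05, adjusted p = 0.843), with Mecom (log2 −0.96) and Cdkn1c (log2 −0.76) lower. Of 26 pan-endothelial genes 5 fell and none rose (11 and 0 adjusted over the list alone, median −0.25, adjusted p = 8.93e-08, but adjusted p = 0.422 with an estimated correlation), a median that was −0.40 without HC GFP− replicate 2, −0.38 without EC GFP− replicate 3, −0.118 after quantile normalization and −0.11 with libraries scaled to an equal sum. In the RNA quality list 3 of 14 fell and none rose (6 and 0 adjusted over the list alone, median −0.51, adjusted p = 0.000104, and adjusted p = 0.28 with an estimated correlation), with a median of −0.32 without EC GFP− replicate 3 and −0.276 after quantile normalization.

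In the limma test, 569 genes differed between HC and EC among GFP− cells, 313 higher in HC and 256 lower, and 258 changed at least 2-fold. The split was 595 and 129 with libraries scaled to an equal sum, which moved the median of all genes from 0.01 to 0.14, and the count was 332 with no filter, 284 when only the GFP− libraries were fitted and 871 with a macrophage score centred within groups as a covariate. It was 91 and 169 without HC GFP− replicates 1 and 3 and 174 and 345 without EC GFP− replicates 1 and 3. With the comparison among GFP+ cells, from other libraries, 228 higher and 162 lower genes were shared where independent lists would share 25.7 and 15.6, and 1 gene went in opposite directions. That gene, named after its values were seen, was St6gal1, which encodes a sialyltransferase (log2 −0.415 among GFP+ and 0.53 among GFP− cells).

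**Figure D4:**
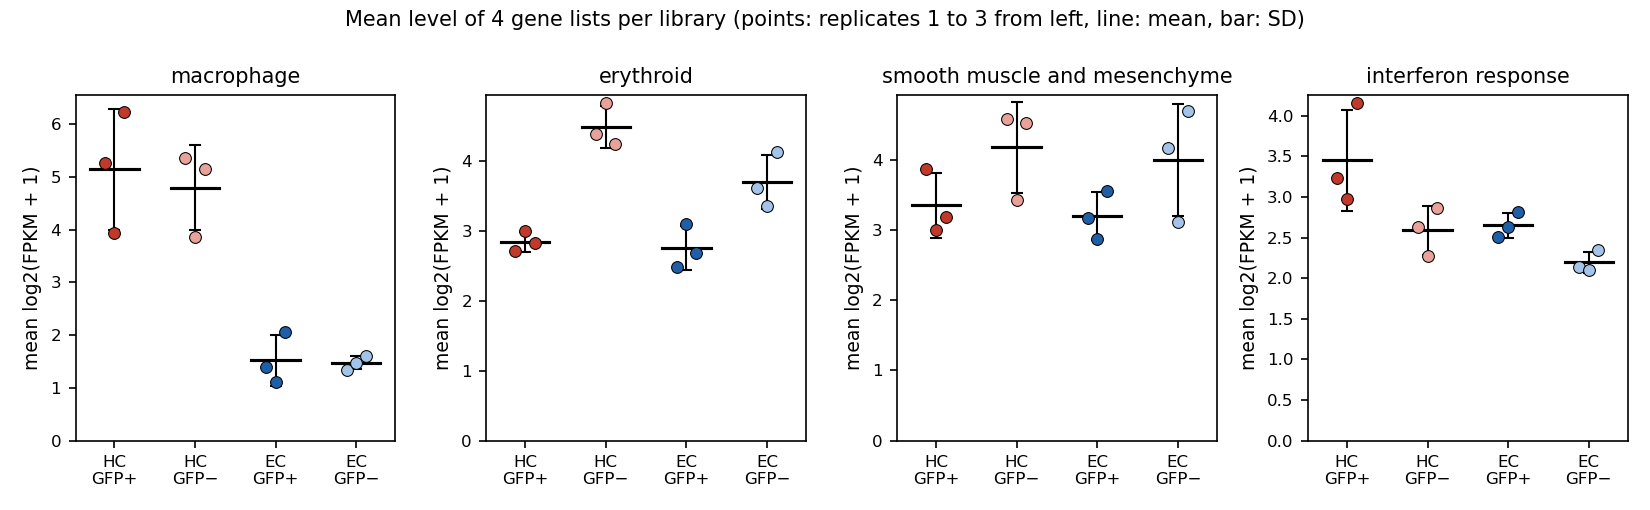
Mean log2(FPKM + 1) of the genes of the macrophage, erythroid, smooth muscle and mesenchyme, and interferon lists (vertical axes) in each library of hematopoietic cluster cells (HC) and endothelial cells (EC), GFP+ and GFP−, with each point a library. The macrophage score lies between 3.87 and 6.23 in the HC libraries and between 1.12 and 2.06 in the EC libraries.

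The effect of GFP itself differed between HC and EC for some genes. Gpr56 rose with GFP by 2.94 in HC and 0.86 in EC, a difference of 2.08 ± 0.26 (adjusted p = 0.00638). Myb rose by 2.63 in HC, while its value of 0.55 in EC did not pass (difference 2.08 ± 0.28, adjusted p = 0.00987, and not called with a pseudocount of 0.1, at 1.56, or with the stricter filter, at 2.08). Fbln5 rose by 3.4 in EC, while its value of 0.73 in HC did not pass (difference −2.67 ± 0.35, adjusted p = 0.00782), and Htra1 rose by 1.47 in HC and 3.92 in EC (difference −2.45 ± 0.27, adjusted p = 0.00399). The list of TGF-beta and BMP genes (median difference −0.41, adjusted p = 4.2e-09) and that of matrix genes (median difference −0.51, adjusted p = 2.49e-12) were the 2 of 10 list calls that held with an estimated correlation (adjusted p = 0.00933 and 0.0201). In them 2 of 21 and 3 of 24 genes had a lower effect in HC and none a higher one (5 and 8 adjusted over the lists alone). In the limma test 70 genes passed, 25 with a higher and 45 with a lower effect in HC, and 54 differed at least 2-fold. The split was 19 and 101 with libraries scaled to an equal sum, which moved the median of all genes from 0.04 to −0.11, and 17 and 55 with median-of-ratios scaling. The count was 43 and 23 without HC GFP+ replicates 1 and 2, 32 and 37 without HC GFP− replicates 1 and 3, 36, 38 and 32 without EC GFP+ replicates 1, 2 and 3, and 42 without EC GFP− replicate 1. It was 39 with a pseudocount of 0.1 or the stricter filter, 130 with the mesenchyme score as a covariate and 109 after a length correction.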

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

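The tests of macrophages within the sort, free macrophage RNA, the correlation with stem cell genes, the left-out library, the scalings and the reassigned deviations were chosen only after the results were seen, while the macrophage covariate, the red cell RNA test and the splits of the libraries were chosen before theirs.

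The results listed first stand out because the effect of GFP differed between HC and EC in a test of the difference itself. Higher effects in HC were those of Gpr56 (difference 2.08 ± 0.26 SE, adjusted p = 0.00638, effects 2.94 in HC and 0.86 in EC) and Myb (2.08 ± 0.28, adjusted p = 0.00987). Spn, the sialophorin gene, followed (1.49 ± 0.22, adjusted p = 0.0134, effects 2.69 and 1.20), though its call ended without HC GFP+ replicate 2 (1.38). Dapp1, a signalling adaptor (1.56 ± 0.24, adjusted p = 0.0181), had effects of 1.81 in HC and 0.25 in EC. Treml2, a receptor of myeloid and lymphoid cells (1.71 ± 0.27, adjusted p = 0.0185), had 1.67 and −0.04, and Pstpip1, a cytoskeletal adaptor (1.74 ± 0.31, adjusted p = 0.0387), had 1.69 and −0.05. These calls ended for Dapp1 without HC GFP+ replicate 1 or 2, HC GFP− replicate 1, EC GFP+ replicate 1 or 2 or EC GFP− replicate 1 (1.47 to 1.59). They ended for Treml2 without HC GFP+ replicate 2 or 3, HC GFP− replicate 1 or 3 or EC GFP+ replicate 1 or 2 (1.59 to 1.77), and for Pstpip1 without any library except HC GFP− replicate 1 (1.54 to 1.86).

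Higher effects in EC were those of Fbln5 (−2.67 ± 0.35, adjusted p = 0.00782, effects 0.73 in HC and 3.4 in EC), Htra1 (−2.45 ± 0.27, adjusted p = 0.00399, effects 1.47 and 3.92), Pi16 (−2.29 ± 0.28, adjusted p = 0.00558, effects 1.26 and 3.55) and the laminin gene Lamc3 (−2.19 ± 0.23, adjusted p = 0.00319, effects 0.57 and 2.76). Pde3a, a phosphodiesterase (−2.29 ± 0.37, adjusted p = 0.0203, effects 0.26 and 2.55), lost its call without HC GFP+ replicate 1 or 2, HC GFP− replicate 3, EC GFP+ replicate 1 or 3 or EC GFP− replicate 1 (−2.30 to −2.18). Agr2, a protein disulfide isomerase (−2.14 ± 0.37, adjusted p = 0.0308, effects 0.05 and 2.20), lost it without HC GFP+ replicate 2, HC GFP− replicate 2 or 3, any 1 EC GFP+ replicate or EC GFP− replicate 2 or 3 (−2.25 to −1.98). With a pseudocount of 0.1 the calls of Myb (1.56), Spn (1.23), Treml2 (2.27), Pstpip1 (2.22), Pde3a (−2.61) and Agr2 (−2.84) ended. Those of Pstpip1 and Agr2 also ended with no filter (1.74 and −2.14), that of Pstpip1 with libraries scaled to an equal sum (1.87) and that of Myb with the stricter filter (2.08).

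Among the gene lists, the GFP effect was lower in HC for the arterial and Notch list (median difference −0.575, adjusted p = 9.09e-15, adjusted p = 0.0874 with an estimated correlation), the matrix list (−0.508, adjusted p = 2.49e-12), the TGF-beta and BMP list (−0.407, adjusted p = 4.2e-09), the pan-endothelial list (−0.289, adjusted p = 6.47e-08, adjusted p = 0.418 with an estimated correlation), the venous list (−0.491, adjusted p = 0.000282, adjusted p = 0.14 with an estimated correlation) and the erythroid list (−0.94, adjusted p = 6.47e-08, adjusted p = 0.27 with an estimated correlation). It was higher in HC for the granulocyte and monocyte list (0.439, adjusted p = 0.0112, adjusted p = 0.531 with an estimated correlation), the S phase list (0.136, adjusted p = 0.00739, adjusted p = 0.339 with an estimated correlation), the interferon list (0.384, adjusted p = 0.0379, adjusted p = 0.743 with an estimated correlation) and the glycolysis list (0.154, adjusted p = 0.0373, adjusted p = 0.59 with an estimated correlation). With libraries scaled to an equal sum the S phase and glycolysis medians were −0.016 and −0.004, neither of them called, against a median of all genes of −0.108. Leaving out 1 library ended the call of the granulocyte and monocyte list without HC GFP+ replicate 3 (0.206) or HC GFP− replicate 2 (0.21), and moved it to 0.83 without HC GFP+ replicate 2 and 0.675 without HC GFP− replicate 1. It ended the S phase call without HC GFP− replicate 3 (0.122) and the glycolysis call without HC GFP+ replicate 2 or 3, HC GFP− replicate 1 or 3, EC GFP+ replicate 1 or 3 or EC GFP− replicate 1 or 3 (0.101 to 0.153), with 0.244 without EC GFP− replicate 2. The interferon call ended without HC GFP− replicate 2 (0.285), EC GFP+ replicate 1 (0.331) or 2 (0.425) or EC GFP− replicate 2 (0.334) or 3 (0.314), and without HC GFP+ replicate 3 (0.069) the direction of its test reversed. The pan-endothelial value was −0.136 without HC GFP− replicate 2 and −0.169 without EC GFP− replicate 3, and the venous value −0.295 without EC GFP− replicate 3. Of the other alternatives, a pseudocount of 0.1 ended the calls of the granulocyte and monocyte (0.149) and interferon lists (0.431). The interferon call also ended with the stricter filter (0.203) and with the macrophage covariate (0.3), and its median was 0.252 with libraries scaled to an equal sum, where the pan-endothelial median was −0.449. The S phase call ended after quantile normalization (0.076), with 0.084 after a length correction. The glycolysis call ended with median-of-ratios scaling (0.112), with 0.061 after quantile normalization.

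The first pattern is the level of macrophage transcripts in the HC libraries, with C1qb at 206 ± 168 and 141 ± 72 FPKM in GFP+ and GFP− HC and the list higher in HC than in EC by 3.81 and 3.65 (adjusted p = 0.217 and 0.156 with an estimated correlation, where neither call held). Free macrophage RNA spread evenly over all sorted populations is argued against, since the lower of these medians, 3.647, lies above 1 by more than the interquartile range of the members, 1.757. Macrophages within the HC sort are a candidate source: the genes deviated together over the 6 HC libraries (median pairwise r = 0.987, against at most 0.353 in 1000 random lists matched on expression), as a macrophage-like subset of cluster cells would also give. The gate would remove cells that lack CD31, CD144, ESAM or Kit, while the labels name no exclusion of CD45+ or myeloid cells. The macrophage score and the mean of Gfi1, Myb, Hlf and Gpr56 deviated in opposite directions over the 6 HC libraries (r = −0.882, exact permutation p = 0.0278, the smallest that the 36 arrangements within groups can give), but Spearman's rho was −0.829 (exact permutation p = 0.139) and r was −0.319 without replicate 2 of each group, so whether the same cells express both stays open.

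The next pattern is the interferon list, higher in GFP+ than in GFP− HC by a median of 0.80. Macrophage content as its whole cause is argued against, since with the macrophage score as a covariate the median was 0.637 (adjusted p = 2.38e-12), above the bound set beforehand for the case that it is not the cause. The share that rests on HC GFP+ replicate 3 stays open, since without it the median of 0.423 (adjusted p = 3.98e-07) lay between the bounds for and against that cause. A difference between the GFP states themselves may remain, as a hypothesis. The list call itself stays weak, since it held with fry (adjusted p = 0.0357) but not with an estimated correlation (adjusted p = 0.273).

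The last pattern is the erythroid list, lower in the GFP+ cells by a median of −1.75 in HC and −0.93 in EC (adjusted p = 0.0874 and 0.273 with an estimated correlation, where neither call held). Scaling between libraries is argued against, since the highest median in HC under the 3 scalings was −1.739. A single pool of free red cell RNA in all libraries stays open: with limma 0 of 12 late erythroid genes (3 at an unadjusted p under 0.05) differed in their ratio to the globins between GFP− HC and GFP− EC, with a median difference of 0.40, which met the condition written beforehand for this cause. Between GFP+ and GFP− HC, however, Slc25a37 (2) and Tspan33 (1.81, adjusted p = 0.00558 each) changed in that ratio, so these values decide neither for nor against it. Erythroid cells in the sorts, which the gates on CD31, CD144 and ESAM would remove where they lack these proteins, and a lower erythroid expression of GFP+ cells, which the design names, may each contribute and were not tested apart, and the list shares Gfi1b with the transition regulators.

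The other splits of the libraries were counted for each comparison. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In GFP+ against GFP− HC the real split gave 566 genes and the highest other 2, in EC 1789 and 1, in HC against EC among GFP+ cells 1898 and 1, and among GFP− cells 569 and 3, with 1 split as large in each case, the real one. For the difference of effects, 6 of 100 splits gave at least the real 70 genes and the highest other gave 2395, so chance is not excluded by this test. Such splits mix the groups themselves, which may be why some call many times the real count, though this was not tested. When only the deviations from additive effects were reassigned to libraries, a test added for that reason, 1 of 100 arrangements gave as many genes, the real one, and the highest other gave 1.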

How the results depend on the processing

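The covariates, the centred scores and the length correction were chosen after the data had been seen, and the other alternatives before the data were examined. Of 7167 values of 314 gene results under the alternatives, 6395 kept their direction and their side of the threshold, 764 no longer passed, 6 newly passed and 2 reversed. Of 1870 values of 75 list results 1687 kept both, 181 no longer passed and 2 reversed, most calls being lost with an estimated correlation or a left-out library. A score used as a covariate for its own list removes that list's change by construction, so such values are not read. Of 130 alternative counts of genes past the threshold 98 lay within 1.5 times the main count. The depth of the libraries is unknown, so weakly expressed genes carry an error that could not be stated, and changes of log2 0.5 were mostly below what the tests recovered in simulation. Except where fewer genes or libraries were used, the cause was not tested.

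A value counts as reversed where the gene's change, or the direction of the list's camera test, changes sign. These were Kit between GFP+ and GFP− EC with libraries scaled to an equal sum (0.01), Cdh5 (−0.11) and the pan-endothelial list (0.008) between GFP+ and GFP− HC with the mesenchyme covariate, and the interferon list in the difference of effects without HC GFP+ replicate 3 (0.069, with 0.069 to 0.541 over the left-out libraries). Medians that changed sign with the test in its former direction, no longer past the threshold, were those of the S phase (0.014) and G2 and M phase lists (0.015) in EC and of S phase (−0.016) and glycolysis (−0.004) in the difference of effects with equal-sum scaling, and the arterial list in HC without HC GFP− replicate 1 (−0.007).

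The count of 566 genes for GFP in HC was 363 with the stricter filter, where fewer genes were tested, 928 with the centred mesenchyme score and 321 to 654 over the left-out libraries. The count of 1789 for GFP in EC was 939 with only the EC libraries fitted and 1004 to 2203 over the left-out libraries. For HC against EC among GFP+ cells, 1898 became 1261 to 2090 over the left-out libraries. Among GFP− cells, 569 became 332 with no filter, 284 with only the GFP− libraries, 871 with the centred macrophage score and 91 to 698 over the left-out libraries. For the difference of effects, 70 became 39 with a pseudocount of 0.1, 39 with the stricter filter, 120 with libraries scaled to an equal sum, 130 with the mesenchyme covariate, 109 with the length correction, 134 with the centred mesenchyme score and 23 to 77 over the left-out libraries.

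No label says that a replicate number marks a shared pool of embryos. Deviations from the group means correlated between libraries of the same number with r from −0.084 to 0.27 (median 0.049, 4 of 18 pairs over 0.1), and 6 of the 12 libraries correlated best with their own number. With the number as a block the counts were 625 for GFP in HC, 1784 in EC, 1917 for HC against EC among GFP+ cells, 603 among GFP− cells and 71 for the difference of effects.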

Other observations

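The tests of the TNF receptor and Hox families were written before their results were seen, although single members of both (Hoxa9, Hoxb5, Tnfrsf1a and Cd40) had been seen in other lists.

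The epithelial and mesonephric, the neural, and the yolk sac and liver lists were not called by camera between GFP+ and GFP− cells of either type. With limma 0 of 10 epithelial and mesonephric genes passed between GFP+ and GFP− HC (1 lower at an unadjusted p under 0.05, adjusted p = 0.877), with a median of 0.17 and a mean of −0.01. In EC 1 of 10 rose, also adjusted over the list alone (median 0.25, adjusted p = 0.379), which was Gata3, a transcription factor gene (4.72 ± 0.192 against 1.68 ± 0.0951 FPKM, log2 1.09 ± 0.20, n = 3, adjusted p = 0.00517). Of 7 neural genes Stmn2 alone passed in each of the 4 group comparisons, also adjusted over the list alone. It was at 69.3 ± 5.54 and 11.9 ± 0.706 FPKM in GFP+ and GFP− HC and at 159 ± 19.1 and 35 ± 4.16 in GFP+ and GFP− EC, while the neural list was not called for GFP (median −0.21 against a mean of 0.20 in HC, adjusted p = 0.703, and −0.215 against 0.009 in EC, adjusted p = 0.895). For yolk sac endoderm and liver 0 of 8 genes passed with limma for GFP in HC (0 at an unadjusted p under 0.05, median −0.18, adjusted p = 0.483), and 0 of 8 in EC (0 at an unadjusted p under 0.05, median −0.196, adjusted p = 0.826).

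Platelet genes and relatives of Ly6a went in more than 1 direction. Of 19 megakaryocyte and platelet genes 3 rose and 1 fell between GFP+ and GFP− HC, also adjusted over the list alone (median 0.30, adjusted p = 0.0639), among them Vwf. Of 5 tested genes of the Ly6 family 2 rose in GFP+ HC, also adjusted over the list alone (median 0.87, adjusted p = 0.196), Ly6a itself and Ly6c1 (log2 0.87 ± 0.17, adjusted p = 0.0145), whose call ended without HC GFP− replicate 2 (0.87) or 3 (0.82). In EC, where Ly6a rose, Gpihbp1, which carries lipoprotein lipase at the capillary wall, fell from 30.5 ± 0.135 to 11.9 ± 1.04 FPKM (log2 −1.29 ± 0.23, adjusted p = 0.00481) in the GFP+ cells. There 1 of the 5 rose and 2 fell, also adjusted over the list alone, with a median of −0.34 and a test in that direction (adjusted p = 0.835) but a mean of 0.09.

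A hypothesis was that Cd27 is higher in GFP+ HC as part of a rise shared by the TNF receptor superfamily. Of 20 other tested members 2 rose and none fell, and the median was 0.114 (95% bootstrap interval −0.08 to 0.39, camera p = 0.0291, 0.0728 adjusted over the 10 tests of both families, and 0.431 with an estimated correlation). The upper end of the interval lies under the bound of 0.5 set beforehand, which argues against a rise of the family of that size. With libraries scaled to an equal sum, however, the median was 0.163 and the interval reached 0.506, past that bound, while the upper ends were 0.39 with median-of-ratios scaling and 0.415 with quantile normalization. The argument therefore depends on the scaling. For GFP in EC 5 of the 20 rose and none fell, with a median of 0.238 (interval −0.161 to 0.725, adjusted p = 0.0497, and 0.431 with an estimated correlation). The 2 members that rose in HC, named after their values were seen, were Tnfrsf19 (10.8 ± 1.22 against 3.9 ± 0.291 FPKM, log2 1.26 ± 0.12, adjusted p = 0.000211) and Tnfrsf26 (log2 0.84 ± 0.16, adjusted p = 0.0118).

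A further hypothesis was that the stem cell genes are higher in GFP+ HC with a shared rise of Hox genes. Of 32 tested Hox genes 1 rose and 1 fell, and the median was −0.147 (95% bootstrap interval −0.277 to −0.108, camera p = 0.0119, adjusted p = 0.0497 and 0.431 with an estimated correlation), which argues against a shared rise. The median was also negative with libraries scaled to an equal sum (−0.116), with median-of-ratios scaling (−0.143) and with quantile normalization (−0.183). Named after their values were seen, Hoxa9 rose (log2 0.71 ± 0.16, adjusted p = 0.0283) and Hoxd9 fell (log2 −0.75 ± 0.12, adjusted p = 0.00405).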
